A study of Arabidopsis thaliana with 4 samples.

How the data were processed

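Total RNA from siliques was extracted with TRIzol and sequenced on an Illumina HiSeq, per the labels' protocols. The deposited files give, per library, each distinct sequence of 15 to 35 nt with its read count, not normalized. The submitters' processing notes name CASAVA 1.8.2 and the genome build TAIR10. Adapter trimming, the aligner and any filter are not given in the sources used here. Of the deposited reads, all but 3, 2, 8 and 2 (wild type, dcl4, nuclear and cytoplasmic line) matched the genome without mismatch, so the files hold genome-matched reads and alternatives based on all reads or on matched reads hardly differ. Reads from transgene parts outside the genome would not be seen.

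Every sequence was matched without mismatches to both strands of TAIR10.1 with an exact matcher written with numba 0.67.0, NumPy 2.4.6 and pandas 2.3.3 in Python 3.11.15. SciPy 1.17.1 gave intervals and Matplotlib 3.10.9 the figures. No coordinates were converted between builds. Reads were split evenly over their matches and counts were divided by the genome-matched reads of 18 to 28 nt, 15196706 in wild type, 17361261 in dcl4, 25296757 in the nuclear and 20733723 in the cytoplasmic line. 3 reads, the floor for a count of 0, correspond to 0.197, 0.173, 0.119 and 0.145 RPM. The annotation used has no transposon features. 25S rRNA was taken as the 4000 nt downstream of each annotated 5.8S gene.

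With 1 library per group no test was run and no p-value is given. Values carry exact Poisson or Wilson binomial 95% intervals and ratios an exact conditional binomial interval, for counting error only, since PCR copies are not independent molecules. Windows of 500 nt with at least 20 RPM in the higher library were counted when they differed at least 4-fold with a pseudocount of 1 RPM, which understates differences of low loci. These are counts by size of difference. Phasing was the share of 21-nt reads in the register most used in wild type, with minus-strand reads shifted by 2 nt.

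Before the data were examined, 9 gene lists, 58 mature sequences in classes, the comparisons and the rule for named loci were fixed. List members with 5 RPM in either library were measured and counted at 2-fold, and each list median was placed among 10000 random lists matched on mean level, drawn with replacement. Log2 ratios of list members and mature RNAs, and their medians, carry a pseudocount of 1 RPM. Folds given for single genes and RNAs do not. Of the 55 miRNA sequences, 54 lay in an annotated gene of the same number and 1 had no read. The rule named, per pair, the 10 most extreme 21-nt windows in each direction, 3 for 22-nt and 24-nt reads, with windows of 1 gene or within 1000 nt named once, the measured list members, and the 10 mature RNAs at 20 RPM or more with the largest log2 ratio. The text gives values for part of the loci so named, and 1 result is not reported here. Chosen after the data were seen were the organelle and pseudogene classes of windows, the levels of the windows lower in dcl4 in the other lines and their split by 24-nt reads, antisense shares, exon and end counts of DCL4, and the chloroplast and 25S rRNA profiles. In the list of transgene and reporter related genes, DCL4 was the 1 measured gene of 5.

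On simulated data, 2000 of 2000 reads cut from the genome were found at their position at each of 21, 22 and 24 nt. In windows redrawn from wild type for the dcl4 against wild type comparison (508 windows tested), 97.0% of 67 windows made 8-fold lower and 100% of 66 made 16-fold lower were called, none of 67 made 2-fold lower, and 0 unchanged windows. A 2-fold change lies below the 4-fold limit by design. The redrawn counts held counting error only and no spread between samples, so the 0 is not a rate of false calls for these libraries. Alternatives covered the denominator (all deposited reads, or reads of 51 listed miRNAs), reads with 1 genome match, full counting of each match, 20 to 22 nt reads, a minimum of 5 RPM, a pseudocount of 5 RPM and windows of 1000 nt. Under another denominator, thresholds were rescaled by the mean ratio of the denominators.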

Results

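Small RNAs were sequenced from siliques (the seed pods) of *Arabidopsis thaliana* Columbia-0 harvested 5 days after pollination. DICER-LIKE 4 (DCL4) is the Dicer enzyme that cuts long double-stranded RNA into 21-nt small interfering RNAs. The 4 libraries came from wild type, the *dcl4-2* mutant (dcl4), and dcl4 plants that expressed either a nuclear or a cytoplasmic form of DCL4 from the Ubq10 promoter (the nuclear and the cytoplasmic DCL4 line). The libraries held 16267721 reads in wild type, 18755127 in dcl4, 27059402 in the nuclear line and 21670047 in the cytoplasmic line. Each group was 1 library, so no difference below has a replicate check, the intervals cover counting error only, and each comparison is between libraries and not between genotypes. Levels are reads per 1000000 genome-matched reads of 18 to 28 nt (RPM), and coordinates are those of TAIR10.1.

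Small RNA libraries do not measure the mRNA of DCL4 itself (AT5G20320, chromosome 5, 6859212 to 6869307), so its expression in the 4 samples is not known from these data. Small RNAs matching the gene were rare in wild type and dcl4, at 0.461 and 1.61 RPM of 22-nt reads. They were abundant in the nuclear line, at 4956 RPM of 22-nt reads (3073-fold above dcl4, 95% interval 2126 to 4625), 1176 RPM of 21-nt reads and 1058 RPM of 24-nt reads. In the cytoplasmic line they stood at 4.92 RPM of 22-nt, 11.2 RPM of 21-nt and 5.11 RPM of 24-nt reads. In the nuclear line 49.1% of the 22-nt reads were antisense to the gene.

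The design asks first how the loss of DCL4 and its 2 forms alter the size profile. The 24-nt class was the largest in each library. It made up 44.7% of all reads in wild type, 32.3% in dcl4, 41.3% in the nuclear line and 54.3% in the cytoplasmic line. The 21-nt share was 20.4% in wild type, 25.8% in dcl4, 23.9% in the nuclear line and 17.1% in the cytoplasmic line, and the 22-nt share was 7.03%, 11.03%, 7.21% and 4.53% in the same order. At this depth the Wilson 95% intervals are narrow, 32.33% to 32.37% for the 24-nt share in dcl4. MicroRNA (miRNA) genes took the largest part of the 21-nt class in each library, 65.9% in wild type, 86.3% in dcl4, 46.2% in the nuclear line and 51.6% in the cytoplasmic line. Outside miRNA genes the order differed: intergenic 21-nt reads stood at 30848 RPM in wild type, 8587 RPM in dcl4, 64904 RPM in the nuclear line and 36068 RPM in the cytoplasmic line. Reads matching structural RNA genes or organelle genomes made up 16.1% of the 18 to 28 nt reads in wild type, 27.96% in dcl4, 17.7% in the nuclear line and 13.6% in the cytoplasmic line.

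**Figure D1:**
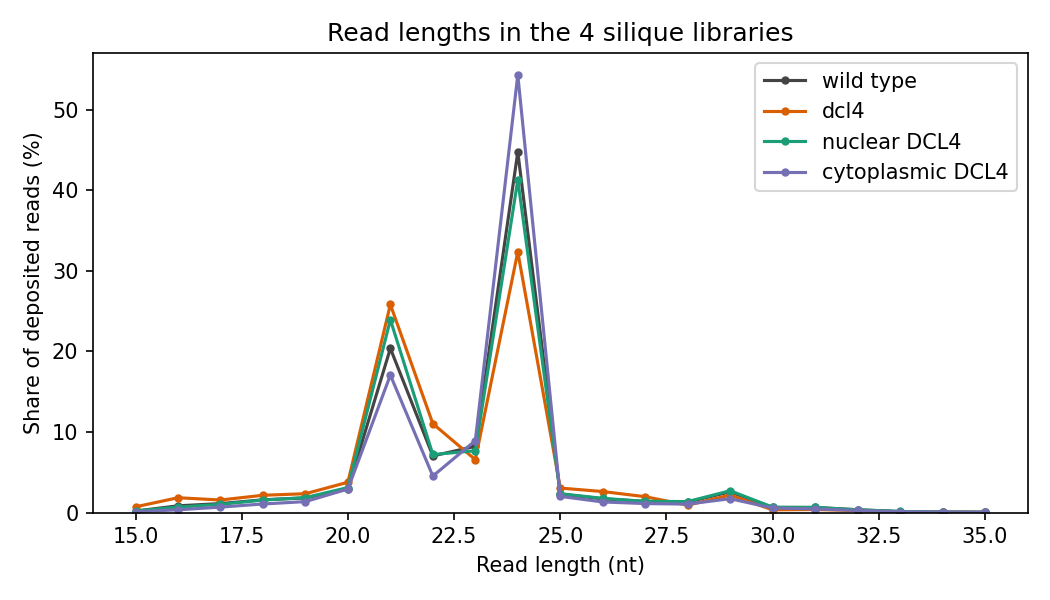
Share of all deposited reads (%, y axis) at each read length (nt, x axis) in each of the 4 libraries, 1 line per library. The 24-nt share runs from 32.3% in dcl4 to 54.3% in the cytoplasmic DCL4 line.

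The loci that produce trans-acting siRNAs (TAS loci), the best known DCL4 substrates, had far fewer 21-nt reads in dcl4 than in wild type. Summed over the 8 loci, 21-nt reads stood at 3270 RPM in wild type and 327 RPM in dcl4, a level 10.0-fold lower (95% interval 9.73 to 10.3). All 6 loci measured at 5 RPM or more were at least 2-fold lower, with a median log2 ratio of -2.79 at percentile 8.01 of 10000 random gene lists of the same size and level. TAS2 (AT2G39681, chromosome 2, 16539384 to 16540417) stood at 879 RPM in wild type and 43.0 RPM in dcl4 and TAS1C (AT2G39675, chromosome 2, 16537288 to 16538277) at 1740 and 106 RPM, while TAS3 (AT3G17185, chromosome 3, 5861491 to 5862437) stood at 441 and 149 RPM. The 22-nt reads of the same loci were 4.66-fold higher in dcl4 (4.55 to 4.76), at 2829 against 608 RPM, and the 24-nt reads 3.11-fold higher (3.02 to 3.19). Of the 20 to 24 nt reads at TAS loci, 21-nt reads made up 74.0% in wild type and 6.55% in dcl4, and 22-nt reads 13.8% and 56.7%. The share of TAS1C 21-nt reads in the phase register most used in wild type, of 21 registers, was 82.7% in wild type and 16.9% in dcl4 (Wilson interval 15.2 to 18.6), where 4.76% falls in a register by chance. TAS3 kept a similar share, at 35.5% and 31.6%. The difference was small when 20 to 22 nt reads were summed, with a log2 ratio of -0.29 in place of -3.32.

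**Figure D2:**
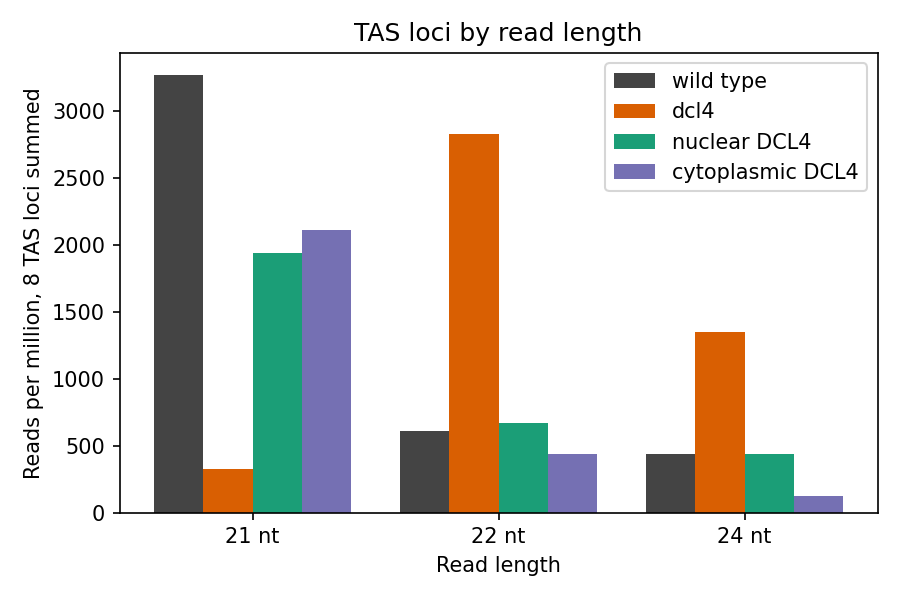
RPM (y axis) summed over the 8 TAS loci, for reads of 21, 22 and 24 nt (x axis), 1 bar per library. The 21-nt bar is 3270 in wild type and 327 in dcl4, and the 22-nt bar is 608 in wild type and 2829 in dcl4.

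Pentatricopeptide repeat (PPR) genes, many of which yield secondary siRNAs, were also lower in dcl4 in 21-nt reads. All 14 measured genes of the 15 in this list were at least 2-fold lower in 21-nt reads, with a median log2 ratio of -4.21 that lay at percentile 0 of the random lists. AT1G62910 (chromosome 1, 23298948 to 23301141) stood at 51.3 RPM in wild type and, with fewer than 3 reads, 0.161 RPM in dcl4, and RPF3 (AT1G62930) at 37.5 and 0.319 RPM. These genes share reads with near-identical relatives: with single-match reads 5 of the 15 were measured, all at least 2-fold lower (median log2 ratio -3.85), and percentiles were not computed for these reads. The auxin receptor genes AFB2 and AFB3 were 10.9-fold and 5.52-fold lower in 21-nt reads (list median log2 ratio -2.42, percentile 20.2). The list log2 ratios in this paragraph carry a pseudocount of 1 RPM and the folds do not, so the log2 ratios are smaller than the folds imply. Both genes were higher in 22-nt reads, AFB3 at 13.6 RPM in wild type and 88.4 RPM in dcl4. ARF4, a tasiRNA target and the 1 measured gene of 10 in its list, stood at 55.5 and 3.69 RPM of 21-nt reads (log2 ratio -3.59, percentile 31). AGO1 and DCL1, the 2 measured genes among 10 other miRNA targets, were 9.47-fold and 4.74-fold lower (median log2 ratio -2.10, percentile 9.16). Among 21 disease resistance genes of the CC-NLR and TIR-NLR classes 3 were measured: AT5G43740 and AT5G38850 were lower, and AT1G12290 was higher in dcl4 at 22.5 against 9.81 RPM, though less than 2-fold when scaled to miRNA reads. This gene overlaps the miRNA gene MIR472. The median log2 ratio of the 3 was -1.86, at percentile 45.2. The random lists were themselves lower in dcl4 to unlike degrees, with medians from -0.486 for the other miRNA targets to -3.14 for the tasiRNA targets, and -0.637 for the TAS loci. Only the PPR genes lay at the edge of the random lists, and their list was drawn up as PPR genes with secondary siRNAs. No member of the RPP4/RPP5 cluster (8 genes) or of the silencing pathway list (8 genes) reached 5 RPM of 21-nt reads in any pair.

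Across the genome, 350 of 529 windows of 500 nt with at least 20 RPM of 21-nt reads were at least 4-fold lower in dcl4 than in wild type, and 9 were higher. Of the 350, 182 were mainly intergenic, 107 mainly in protein-coding exons and 27 in annotated pseudogenes. The most extreme was a mainly intergenic window overlapping AT2G25905 (chromosome 2, 11047001 to 11047500), with 201 RPM in wild type and 3.69 RPM in dcl4. An exonic window of AT1G13760 (chromosome 1, 4720001 to 4720500) stood at 764 and 23.4 RPM, one at AT3G16930 (chromosome 3, 5778501 to 5779000) at 61.1 and 0.922 RPM, and an intergenic one on chromosome 5 (9114501 to 9115000) at 45.3 and 0.346 RPM. Other named windows lay at AT5G22860, a serine carboxypeptidase gene (56.3 and 1.09 RPM), at AT1G47880, a pseudogene of a receptor-like protein (126 and 3.66 RPM), and in a mainly intergenic window overlapping AT2G24560, a lipase gene (53.8 and 0.634 RPM). Not all these losses were limited to 21-nt reads. The chromosome 5 window was also lower in 22-nt (40.4 and 0.979 RPM) and 24-nt reads (391 and 8.81 RPM). The AT5G22860 window was also lower in 22-nt reads (48.4 and 3.11 RPM). For the other windows named here only 21-nt values are given. The windows higher in dcl4 were 5 exonic and 4 of miRNA genes. The most extreme were exonic windows of BAM1 at 0.263 and 105 RPM, BAM3 at 0.0658 and 34.6 RPM, and AP2 at 1.78 and 38.6 RPM. Those of miRNA genes included MIR165a (chromosome 1, 79001 to 79500) at 14.2 and 129 RPM and MIR408 (chromosome 2, 19319501 to 19320000) at 722 and 2967 RPM. In dcl4, 100% of the reads in the MIR165a window had a single genome match. Mature miR165a has 2 matches and so is not what this window counts. It stood at 30847 RPM in wild type and 50942 RPM in dcl4. Scaled to miRNA reads, 5 windows were higher, and the MIR408 window, at a log2 ratio of 1.31, was not among them. In 328 of the 350 windows, 24-nt reads outnumbered 21-nt reads in wild type. With a minimum of 5 RPM, 640 windows were lower and 40 higher.

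A few protein-coding genes had abundant 22-nt siRNAs in dcl4 and almost none in wild type. BAM1 (AT5G65700, chromosome 5, 26281642 to 26285413) and BAM3 (AT4G20270, chromosome 4, 10949573 to 10953113), receptor-like kinases related to CLAVATA1, had 929 and 1026 RPM of 22-nt reads in dcl4 against 0.526 and 0.0658 RPM in wild type. AP2 (AT4G36920, chromosome 4, 17400610 to 17403469), a floral homeotic transcription factor and miR172 target, had 776 RPM against 0.855 RPM. The ratios were 1765 for BAM1 (896 to 4090), 908 for AP2 (531 to 1705) and, against a single wild-type read, 15585 for BAM3 (2797 to 615614). The 22-nt class made up 72.8% of the 20 to 24 nt reads of BAM1 in dcl4, 74.2% of BAM3 and 68.2% of AP2, and 51.3%, 55.7% and 46.4% of the 22-nt reads were antisense to the gene. In the nuclear line AP2 kept 82.2 RPM (78.7 to 85.8), while BAM1 stood at 0.593 and BAM3 at 0.395 RPM. In the cytoplasmic line AP2 stood at 0.241, BAM1 at 0.531 and BAM3 at 0.0482 RPM.

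**Figure D3:**
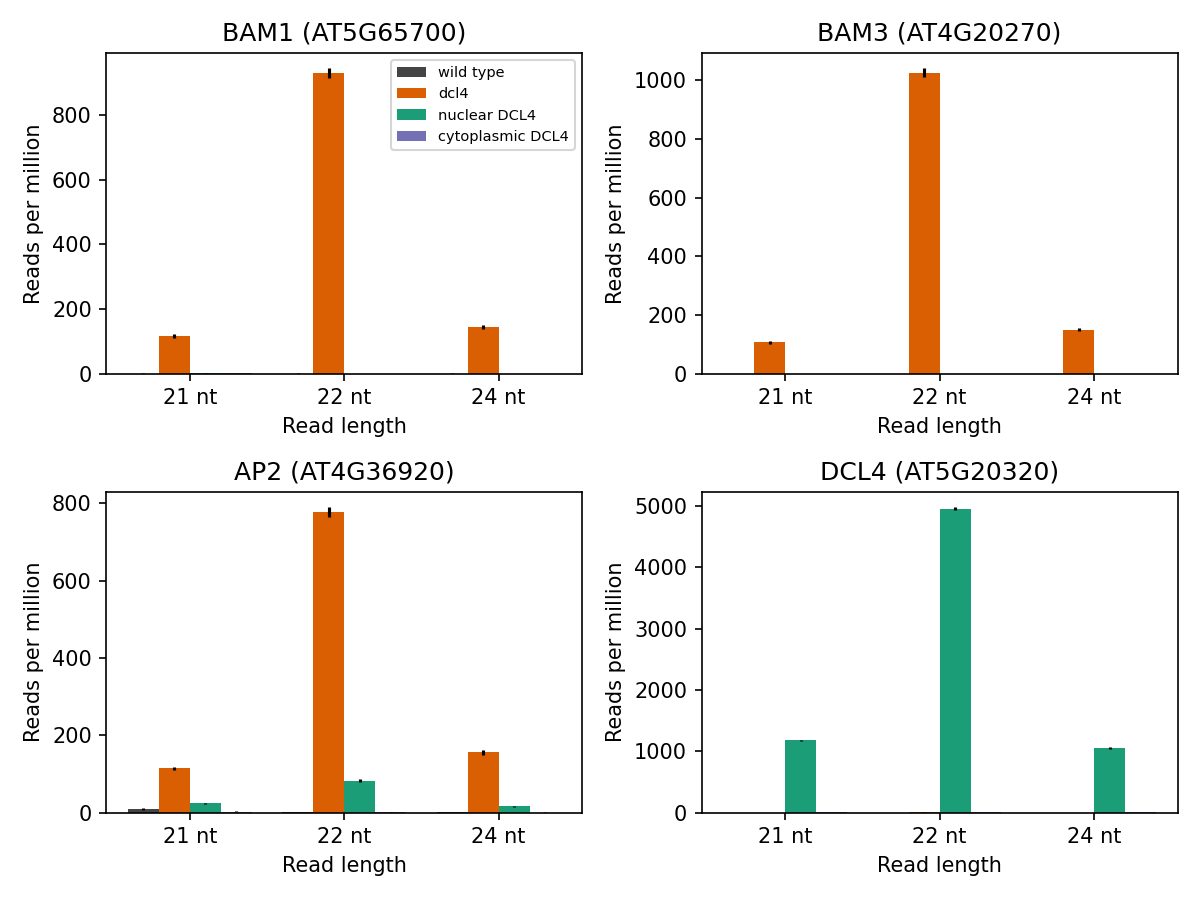
RPM (y axis) of 21, 22 and 24 nt (x axis) at 4 genes, 1 bar per library, with exact Poisson 95% intervals. BAM1, BAM3 and AP2 reach 929, 1026 and 776 in 22-nt reads in dcl4, and DCL4 reaches 4956 in the nuclear DCL4 line.

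Over all 22-nt windows, 154 of 590 were at least 4-fold higher in dcl4 than in wild type and 22 were lower. Of the higher ones, 109 lay mainly in annotated pseudogenes; transposons are not annotated separately here. Of these 109, 48 were still counted when scaled to miRNA reads and 11 with single-match reads; their median level in dcl4 was 29.7 RPM. Their summed 22-nt reads stood at 118 RPM in wild type, 4390 RPM in dcl4, 78.0 RPM in the nuclear line and 51.1 RPM in the cytoplasmic line. Other sizes were higher in dcl4 too, unlike the 21-nt reads of the TAS loci. In the same windows 21-nt reads stood at 64.7 RPM in wild type and 436 RPM in dcl4, and 24-nt reads at 385 and 1163 RPM. The most extreme of these windows in 22-nt reads against the nuclear line was at AT3G43862 (chromosome 3, 15715501 to 15716000), with 1.61 RPM in wild type and 111 RPM in dcl4. Among 24-nt windows 210 of 1906 were lower and 26 higher. A window at AT3G57480 (chromosome 3, 21277001 to 21277500) stood at 55.2 RPM in wild type and had no read in dcl4. It stood at 0.0395 RPM in the nuclear and 0 in the cytoplasmic line, so neither line regained these reads. The intergenic window on chromosome 5 (9114501 to 9115000) did regain 24-nt reads. It stood at 391 RPM in wild type, 8.81 RPM in dcl4, 411 RPM in the nuclear and 728 RPM in the cytoplasmic line. Against dcl4, 192 of 1696 24-nt windows were higher in the nuclear line and 22 lower. In the cytoplasmic line 371 of 1861 were higher and 30 lower.

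Mature miRNAs took a larger share of the dcl4 library. The median log2 ratio over 26 miRNAs at 20 RPM or more was 0.72, and 25 of the 26 lay above 0. Scaling to the listed miRNAs shifts every dcl4 to wild type ratio by -0.73. Beyond this median, miR408, a copper-responsive miRNA, stood at 598 RPM in wild type and 2651 RPM in dcl4, miR398b at 6298 and 14204 RPM, and miR390a, the trigger of TAS3 siRNAs, at 159 and 516 RPM. The tasiRNA tasiR-ARF-D7 stood at 44.4 and 0.634 RPM. siR255 had 159 reads in wild type and none in dcl4, at least 60.6-fold lower against a floor of 3 reads, and miR822, which DCL4 processes, had 115 and none, at least 43.8-fold lower. By class, the median log2 ratio in dcl4 was 0.62 for 17 measured conserved miRNAs (percentile 99.9), 0.51 for 10 young (99), 0.85 for 5 nutrient-responsive (98.8), 1.18 for 2 tasiRNA triggers (92.4) and 0.18 for the pollen miRNA miR845a (72.9). It was -1.41 for 2 DCL4-dependent miRNAs (15.5) and -4.16 for 2 tasiRNAs (0.005). The random lists for these classes were drawn from all sequences of 20 to 24 nt with like level, so the miRNA percentiles carry the shift of the whole class. miR869.2, the other measured DCL4-dependent miRNA, stood at 67.3 RPM in wild type, 81.6 RPM in dcl4, 57.7 RPM in the nuclear and 91.3 RPM in the cytoplasmic line. Of the 10 measured young miRNAs 1, miR840, was at least 2-fold lower in dcl4, at 5.00 RPM in wild type and 0.115 RPM in dcl4. It stood at 2.65 RPM in the nuclear and 2.75 RPM in the cytoplasmic line.

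The nuclear and cytoplasmic lines ask where in the cell DCL4 has to be for these small RNAs. The libraries do not separate the place of DCL4 from its expression level or the insertion site of the transgene in each line. Both had more TAS 21-nt reads than dcl4. The nuclear line was 5.93-fold higher (5.77 to 6.10), at 1940 RPM, and the cytoplasmic line 6.46-fold higher (6.28 to 6.64), at 2112 RPM, which is 0.593 and 0.646 of wild type. Scaled to miRNA reads these were 0.730 and 1.02, so whether the cytoplasmic line lay below wild type depends on the scaling. The 22-nt TAS reads were 672 RPM in the nuclear line and 438 RPM in the cytoplasmic line, and the 24-nt TAS reads 436 and 126 RPM. With 20 to 22 nt reads summed, the ratios to dcl4 turned to a log2 of -0.28 and -0.31. All 11 measured PPR genes in the nuclear and all 13 in the cytoplasmic comparison were at least 2-fold above dcl4, AT1G62910 at 25.4 and 30.9 RPM. Their median log2 ratios of 3.62 and 3.60 lay at percentile 100 of the random lists, while those of the TAS loci, 2.03 and 2.18, lay at percentiles 57.3 and 80.0. With single-match reads 4 PPR genes were measured in each comparison, all at least 2-fold above dcl4. Over all gene lists, 22 measured members were at least 2-fold higher in the nuclear line than in dcl4 and 1 lower, and 27 were higher in the cytoplasmic line and 1 lower. Both counts of higher members include DCL4 itself, and most 21-nt windows of the genome were also higher in both lines, as given below. The lower member, AT1G12290, was within 2-fold when scaled to miRNA reads. ARF4 stood at 24.9 and 12.7 RPM and AFB3 at 26.4 and 29.3 RPM. tasiR-ARF-D7 stood at 31.98 and 34.1 RPM. The median log2 ratio of mature miRNAs to dcl4 was -0.97 and -1.32, where scaling to miRNA reads shifts ratios by 1.03 and 1.40. Beyond the median, miR408 stood at 823 RPM in the nuclear and 366 RPM in the cytoplasmic line.

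Of 642 windows, 507 were at least 4-fold higher in 21-nt reads in the nuclear line than in dcl4 and 8 lower, and of 519 windows 300 were higher in the cytoplasmic line and 13 lower. Scaled to miRNA reads the counts of higher windows were 569 in the nuclear and 543 in the cytoplasmic line. The sets of 507 and 300 had 251 windows in common. Among the 464 windows tested in both comparisons 330 and 254 were higher, so that independent lists would share 181, a value that leaves out the shared dcl4 library. Unchanged libraries simulated against that dcl4 library shared 0 in each of 100 draws, a value that leaves out the effects and the spread between samples. Part of the 251 may therefore come from the shared library. Among the 350 windows lower in dcl4, the median ratio to wild type was 2.02 in the nuclear line and 0.727 in the cytoplasmic line. Scaled to miRNA reads it was 2.48 and 1.15, which turns the direction for the cytoplasmic line. In the nuclear line 180 of them exceeded wild type more than 2-fold, and in the cytoplasmic line 1 did, or 225 and 21 scaled to miRNA reads. In the 22 windows where 24-nt reads did not outnumber 21-nt reads, the median ratios were 0.575 and 0.549. The AT2G25905 window stood at 502 RPM in the nuclear and 202 RPM in the cytoplasmic line.

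Set against each other, the lines differed little at TAS loci, with the nuclear line at 0.919 of the cytoplasmic one (0.907 to 0.930) in 21-nt reads. With 20 to 22 nt reads the log2 ratio was 0.03 in place of -0.12. In 21-nt reads the median log2 ratio of the 6 measured TAS loci was -0.154, at percentile 3 of the random lists. Those lists had a median of 0.823, so the TAS loci were low in the nuclear line relative to genes of like level. In 21-nt reads none of the 13 measured PPR genes differed 2-fold (median log2 ratio -0.24, percentile 17.5), and of all gene list members DCL4 alone did. In 24-nt reads all 5 measured TAS loci were at least 2-fold higher in the nuclear line, with a median of 3.83-fold, and in 22-nt reads 2 of 5 were. The auxin receptor gene measured in each of these sizes was higher by a log2 of 1.03 (22 nt) and 1.10 (24 nt), which the shift of -0.365 from miRNA scaling takes under 2-fold. Of 676 windows, 26 were higher in the nuclear line and 41 lower; scaled to miRNA reads these counts were 17 and 68. The median log2 ratio over the 676 windows was 1.23, so the typical window was higher in the nuclear line without reaching 4-fold. Of the 41 lower windows 32 lay in organelle genomes outside structural RNA genes, and without organelle and structural windows 5 were lower. The highest ratio of the nuclear to the cytoplasmic line was in a window of DCL4 itself. An exonic window of PIRL1 (chromosome 5, 1762501 to 1763000) stood at 116 RPM of 21-nt reads in the nuclear and 12.8 RPM in the cytoplasmic line, though only 0.102% of its reads had a single genome match. MADS-box genes AT4G36590 and AT1G33070 had windows at 102 and 192 RPM in the nuclear and 22.4 and 43.1 RPM in the cytoplasmic line, less than 4-fold when scaled to miRNA reads, and wild type had 118 and 112 RPM. Lower in the nuclear line was the window of MIR833a and MIR833b (chromosome 1, 29525001 to 29525500), at 2.17 RPM against 20.02 RPM, with 4.08 RPM in wild type and 5.07 RPM in dcl4.

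Most of the 21-nt windows higher in the cytoplasmic than in the nuclear line lay in organelle genomes. Mitochondrial 21-nt reads as a whole were not higher, at 257 RPM in the nuclear and 241 RPM in the cytoplasmic line. Chloroplast 21-nt reads outside rRNA and tRNA genes stood at 413 RPM in wild type, 530 RPM in dcl4, 1088 RPM in the nuclear line and 4747 RPM in the cytoplasmic line. The window over rpl33 and rps18 (chloroplast, 67501 to 68000) stood at 2.77 RPM in dcl4, 91.5 RPM in the nuclear and 465 RPM in the cytoplasmic line, and the one over psbT, psbN and psbH, photosystem II genes (74001 to 74500), at 7.18, 45.2 and 306 RPM. A window of the nuclear F-box gene AT1G47300 (chromosome 1, 17339501 to 17340000) stood at 0.173, 11.9 and 74.5 RPM, but 12.0% of its reads had a single genome match.

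**Figure D4:**
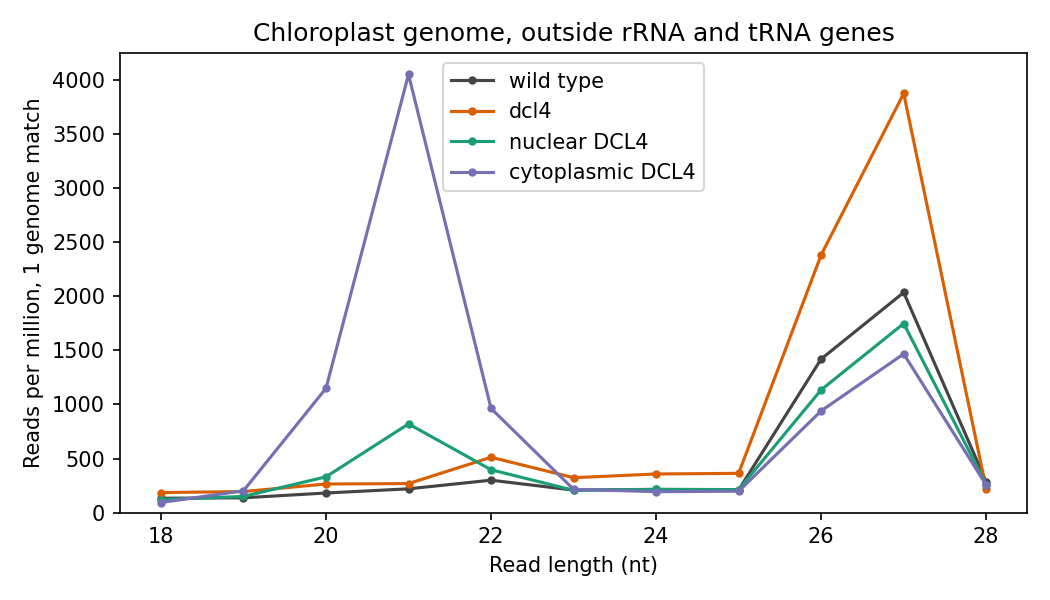
RPM of reads with a single genome match on the chloroplast genome outside rRNA and tRNA genes (y axis) by read length (nt, x axis), 1 line per library. At 21 nt the cytoplasmic DCL4 line reaches 4051 and the nuclear line 820, and at 27 nt dcl4 is the highest library at 3875.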

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

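None of the tests in this part was planned: all were written down after the results they measure had been seen.

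At 4 of the windows that the rule named for nuclear against cytoplasmic, the lines differed from dcl4 by at least 2-fold in opposite directions. The difference was not tested, since each line is 1 library. The 21-nt window at MIR841b (chromosome 4, 2184001 to 2184500) stood at 9.45 RPM in dcl4, 3.18 RPM in the nuclear and 31.98 RPM in the cytoplasmic line, a difference of log2 ratios of -2.98, and that at MIR841a (chromosome 4, 7885001 to 7885500) at 8.50, 3.18 and 22.6 RPM, a difference of -2.50. Wild type had 5.36 and 5.43 RPM. In the cytoplasmic line 40.4% of the MIR841b and 16.6% of the MIR841a reads had a single genome match, so these windows may share reads. Scaling to miRNA reads shifts nuclear to dcl4 ratios by 1.03, so the lower levels of MIR841b (log2 ratio -1.32) and MIR841a (-1.18) in the nuclear line are then less than 2-fold. The 24-nt window at AT1G10745 (chromosome 1, 3573001 to 3573500) stood at 5.59, 33.8 and 0.0482 RPM, a difference of 5.05, with 38.4 RPM in wild type. The 24-nt window at ARP9 (chromosome 5, 17469501 to 17470000) stood at 10.3, 0 and 54.3 RPM, a difference of -5.79, with 53.0 RPM in wild type. Reads of 29 nt lie outside the lengths compared in the report. They made up 2.58% of the wild type library, 2.17% of dcl4, 2.71% of the nuclear and 1.72% of the cytoplasmic line.

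The 21-nt chloroplast reads of the cytoplasmic line stood out. More plastid RNA fragments of every size would raise other lengths, but the median ratio to dcl4 over 8 other lengths was 0.544 (range 0.379 to 1.17); 20 and 22 nt, next to the peak, were left out of that median and were also higher, at 1149 against 264 RPM and 962.5 against 511 RPM. Reads shared with nuclear copies of plastid DNA are argued against by reads with a single match, which were 15.1-fold higher than in dcl4. Breakdown of single-stranded transcripts would leave 1 strand, but 39.4% of the 21-nt reads lay on the minor strand of their window, against 8.49% in dcl4, and in the nuclear line, where these reads were 3.06-fold above dcl4, the share was 34.3%. Dicing of double-stranded plastid RNA by the expressed DCL4 is a hypothesis that stays open, with 1 library of each line.

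DCL4 siRNAs were abundant in the nuclear line. Their 22-nt density in introns was 0.265% of that in the coding sequence, which argues against transcripts that keep introns. In the annotated untranslated regions, 598 nt in all, no 22-nt read was found, a density of 0% of that in the nearest 300 coding nt at each end, where 822 reads lay; 3 reads would have made 0.366%, and 1 read lay in a further untranslated exon of 31 nt left out of the test. The test first used the whole coding sequence and was changed after that was seen, since density is lower toward both ends. A fall that continues past the coding ends could also leave the untranslated regions of a full-length transcript empty, so the test cannot decide. Full-length transcripts of the resident gene stay open as a source. Silencing of the transgene transcript may explain the reads, and the design has no second nuclear line to test it.

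The 22-nt reads in 109 pseudogene windows were higher in dcl4. An error of the scaling would move all 22-nt windows alike, but the other 481 tested windows had a median log2 ratio of -0.41 (quartiles -0.91 to 0.47), against 4.17 in the 109. Spread of reads over related copies is argued against by the 84 of these windows that reads with several matches select on their own, whose single-match reads, not used in the choice, were 36.3-fold higher (31.6 to 41.9); 63 of the 69 with at least 10 such reads were at least 4-fold higher, and 15 had fewer and stay open. Both tests replaced earlier forms after these were seen: sums over windows chosen on the same reads, and before that the number still called, 48 of the 109 scaled to miRNA reads and 11 with single-match reads, so the number of windows depends on both settings. Processing by another Dicer in the absence of DCL4 was not tested.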

How the results depend on the processing

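The alternatives for gene lists scaled to miRNA reads, mature small RNAs, the overlap, size classes, single loci, levels relative to wild type and windows without organelles were chosen after seeing the data. No paired analysis was possible because each group is 1 library and no test was run. Of 146 values of the main results under alternatives, 95 stayed within their counting interval or 1.5 times the count, 46 moved and 5 reversed. Of 791 values of single windows, genes and mature RNAs under alternatives, 0 reversed and 481 moved outside their counting interval, which is narrow at this depth and ignores biological spread.

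TAS log2 ratios scaled to miRNA reads were -4.05 (dcl4 against wild type), 3.60 (nuclear against dcl4), 4.09 (cytoplasmic against dcl4) and -0.49 (nuclear against cytoplasmic). Scaled to all deposited reads, cytoplasmic against dcl4 gave 2.74 and nuclear against cytoplasmic -0.156. With 20 to 22 nt reads they were -0.29, -0.28, -0.31 and 0.0345, the last 3 with the sign turned: the 22-nt reads added by this choice are higher in dcl4 than in the lines, and higher in the nuclear than in the cytoplasmic line (672 and 438 RPM). Windows lower, scaled to miRNA reads, numbered 2, 5 and 68 (nuclear against dcl4, cytoplasmic against dcl4, nuclear against cytoplasmic). Windows higher with this scaling numbered 5 (dcl4 against wild type), 569 (nuclear against dcl4), 543 (cytoplasmic against dcl4) and 17 (nuclear against cytoplasmic). At a minimum of 5 RPM, 640, 19 and 33 were lower and 40, 1079 and 787 higher in the first 3 pairs, since more windows are tested. With a pseudocount of 5 RPM, 5 (nuclear against dcl4) and 20 (nuclear against cytoplasmic) were lower, and without structural and organelle windows 5 were lower in the last pair. Without structural and organelle reads, the 21-nt and 24-nt shares were 24.1% and 55.3% in wild type, 35.4% and 44.7% in dcl4, 28.6% and 51.7% in the nuclear and 17.7% and 64.3% in the cytoplasmic line. With single-match reads, 18 list members were lower in dcl4 in place of 27, and 15 and 18 higher in the nuclear and cytoplasmic lines in place of 22 and 27, since fewer PPR genes are measured. List members in the less frequent direction numbered 0 in place of 1 in the first 3 pairs when scaled to miRNA reads. The miRNA medians were 0.70, -0.96, -1.27 and 0.29 scaled to all deposited reads and 0.94, -1.16, -1.58 and 0.40 outside structural and organelle reads. Relative to wild type and scaled to miRNA reads, TAS levels were 0.730 (nuclear) and 1.02 (cytoplasmic), and the median over the windows lower in dcl4 was 2.48 and 1.15, so that both cytoplasmic values lie above 1 in place of below. Scaled to all deposited reads, the cytoplasmic TAS level was 0.661. The overlap was 420 scaled to miRNA reads and 524 at 5 RPM. Scaling to miRNA reads shifts log2 ratios by -0.73, 1.03, 1.40 and -0.36 in the 4 pairs, and other causes were not tested.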

Other observations

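The 25S rRNA profile and AGO2 were chosen after their values were seen.

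In dcl4, 22-nt reads were also abundant at the 25S rRNA region. On the chromosome 3 copy (14199917 to 14203916) they stood at 2577 RPM in wild type, 18757 RPM in dcl4, 4342 RPM in the nuclear and 2340 RPM in the cytoplasmic line. Antisense reads made up 3.88%, 42.7%, 21.4% and 9.91% of them, in the same order. Of the genes outside the windows named first, AGO2 had 14.6 RPM of 22-nt reads in dcl4 and 0.461 RPM in wild type.

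A single 24-nt window at AT5G42410 (chromosome 5, 16964501 to 16965000) stood at 63.4 RPM in the nuclear line, 0.403 RPM in dcl4, 0.0658 RPM in wild type and 0 in the cytoplasmic line. The intergenic 24-nt window on chromosome 2 (13127001 to 13127500) stood at 40.6 RPM in wild type and had no read in the other 3 libraries.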
